A study of Rattus norvegicus with 3 samples.

How the data were processed

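RNA was measured in 3 libraries of commissural neurons from the spinal cord of rat embryos of embryonic day 13, cultured for 2 days. Per the labels, polyadenylated RNA was made into stranded libraries and sequenced with paired reads of 50 bp. The submitters' processing notes name FastQC, Trimmomatic 0.22, STAR and the genome build rn6. The tool that computed FPKM, its annotation, its use of strand and its treatment of reads that map to several places are not given in the sources used here. The authors deposited 1 table of FPKM values, with a column per library and 26353 entries, of which 5754 had no gene symbol and 6742 no description. FPKM values are scaled by transcript length and by the authors' count of mapped fragments, so no counts, absolute depths or counting intervals were computed. Summed FPKM was 25032100 in library 1, 19897900 in library 2 and 26236600 in library 3, and without the entries above 10000 FPKM it was 433285, 477484 and 430187. Values identical between libraries made up 0.0744% to 0.297% of the 8069 described genes, so all 3 libraries were counted as separate samples.

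All libraries form 1 group, and no comparison between groups was possible. Values were used as deposited, as log2(FPKM + 0.1). The 17611 entries above 0 in at least 1 library were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), one-sided against 1 FPKM, with a robust prior and a mean-variance trend, and Benjamini-Hochberg adjustment at a threshold of 0.05. For 95 planned pairs of related genes, limma tested the log2 ratio within each library, two-sided, with a prior estimated together with 5000 random pairs and Benjamini-Hochberg adjustment over the 95; 90 passed. An exact sign-flip test on 3 libraries could not go below p = 0.25, so limma's model across genes was used. These tests cover the spread between libraries and not errors of length, GC content or mapping that all libraries share. Differences between cell class lists were averaged over the 3 libraries without a p-value. Tests were checked on simulated data. Among 17611 simulated genes, 47 of 50 at 1.5 times the level of 1 FPKM and 49 of 50 at 2 times were called, as were 3 of 50 at exactly 1 FPKM, and 7 of 11279 calls were false. Among simulated pairs, 2 of 50 without a difference, 24 of 50 with a ratio of 1.2, 45 of 50 with 1.5 and 50 of 50 with 2 were called. These pairs were drawn from genes above 1 FPKM, with independent noise for each gene. The rates need not hold for pairs of lower genes or where a library shifts many genes together.

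The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names every matched gene of the Dock, Elmo, GTPase and Shh reception lists, the 4 highest and 2 lowest of each other list (all where it has 6 or fewer), and the 10 genes with the highest mean and the 10 with the largest SD among those with a mean of at least 5 FPKM; some were given only as counts. By this rule the 10 highest and 10 most variable entries are nearly all unnamed. Neo1, Robo1, Robo2, Dscam, Unc5b and Unc5d are named as members of the planned pairs. The highest and most variable entries with a description, Lyn, Egr1, Gapdh, Hspa8, and the genes first named in the closing section fall outside the rule and were chosen after their values were seen. Of 264 list entries, 7 matched no symbol and were not analysed under these names, among them Plxna1, Lhx2, Prrxl1, Gbx1, Slc18a3 and Acta2. Some list genes are not reported here: counts given for the genes reported leave them and their pairs out, as does the adjustment over the list alone beside such counts, while totals over all lists and pairs and the differences between cell class lists include them. A further 4 genes were matched by another symbol, with the RefSeq names of assembly GRCr8 used for names alone. For 4 genes with more than 1 entry, the entry with the highest mean was taken. Gene positions were not used here. Close relatives such as Actb and Actg1 or the alpha globins could share reads, so their single values are uncertain; the constitutive chaperone gene Hspa8 had only 3.68 ± 0.222 FPKM, while Gapdh had 578 ± 62.5. Whether an FPKM of 0 is a failed estimate is not known, so such genes are only said to be listed at 0. Of 74 ribosomal protein symbols, 1 (Rps17l) was at 0, and the cause was not tested.

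The alternatives were other pseudocounts (0.01 and 1), libraries rescaled to a common sum or upper quartile, other filters, levels of 0.5 and 5 FPKM, another variance prior, a margin of 1.5-fold for pairs, medians for lists and each library left out. Tests restricted to entries with a description were added after the data were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.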

Results

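Polyadenylated RNA was sequenced from commissural neurons of the rat spinal cord, the neurons whose axons cross the ventral midline during development. The cells came from embryos of embryonic day 13 and were kept for 2 days in culture. The series holds 1 group of 3 libraries, called libraries 1, 2 and 3 here by the replicate numbers in the labels, and no treated or control group, so genes were compared with each other within the same libraries. Values are the authors' FPKM (fragments per kilobase of transcript scaled to the number of mapped fragments). Nothing in the labels says that the 3 libraries came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Of 17611 table entries above 0 in at least 1 library, 11218 (63.7%) lay above 1 FPKM in limma's one-sided moderated test with Benjamini-Hochberg adjustment, and 6393 did not. Of the 242 distinct genes matched from the lists fixed before the data were examined, 164 lay above 1 FPKM. With each library rescaled to a common sum, most of which a few unnamed features hold, 49 did, and 28 of the 40 lists had over 1.5 times fewer of their reported genes above 1 FPKM. Across 8069 genes with a description and a mean of at least 5 FPKM, Pearson's r of log2 values was 0.987 between libraries 1 and 2, 0.994 between 1 and 3 and 0.987 between 2 and 3, over genes, which are not independent replicates. FPKM does not give the absolute depth of a library. The relative value of a single read was estimated from entries above 1 FPKM in 2 libraries and at 0 in the third. Only entries with a ratio near 1 were kept, as if they held equal numbers of reads, so the estimate stays close to 1 by construction. Its median was 1.02 for library 1 over library 2 (6 of 14 entries) and 0.885 for library 1 over library 3 (6 of 11 entries).

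The title of the series places polarized Dock activity in Sonic hedgehog (Shh) guided axon growth, and the first question is which Dock genes these cultures express. The RNA is of whole cultures, in which progenitor, proliferation and macrophage genes were also found (below), so the cell source of each gene is not known. Dock proteins are exchange factors that load Rac or Cdc42 with GTP. Dock4 (ENSRNOG00000004823) had 15.1 ± 2.47 FPKM (SD, n = 3), Dock3 9.02 ± 0.886, Dock11 7.41 ± 0.552 and Dock1 2.66 ± 0.240 FPKM. These 4 of the 10 Dock genes reported here lay above 1 FPKM in limma's test with Benjamini-Hochberg adjustment over all genes, and 4 did when adjusted over the list alone. With each library rescaled to a common sum, 0 of the 10 passed limma's test and 0 had an unadjusted p under 0.05. Dock6 had 1.2 ± 0.127 FPKM and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0840). Dock9 had 0.740 ± 0.0436, Dock10 0.687 ± 0.0208, Dock5 0.423 ± 0.0513, Dock8 0.230 ± 0.0700 and Dock2 0.217 ± 0.0551 FPKM.

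Within each library, Dock4 exceeded Dock3 by 1.66-fold (95% interval 1.42 to 1.94, limma, Benjamini-Hochberg adjusted p = 7.80e-04, higher in 3 of 3 libraries), on the log2(FPKM + 0.1) scale on which all fold differences here are given and which understates those of low genes; this call was lost when a difference of at least 1.5-fold was tested. Dock4 exceeded Dock11 by 2.01-fold (1.65 to 2.45, limma, Benjamini-Hochberg adjusted p = 5.61e-04, 3 of 3 libraries) and Dock1, the founding member of the family, by 5.47-fold (4.22 to 7.08, limma, Benjamini-Hochberg adjusted p = 5.46e-05). The pairs of Dock genes share members and are not independent, and 79 of all 84 pairs reported here differed past the threshold. Of the 45 pairs of Dock genes reported here, 43 did. Dock2 and Dock8 did not (log2 ratio -0.05, interval -0.26 to 0.15), nor did Dock9 and Dock10. Dock3 exceeded Dock11 by 1.21-fold (1.03 to 1.43, limma, Benjamini-Hochberg adjusted p = 0.0319), a call that was lost when any 1 library was left out and when a difference of at least 1.5-fold was tested. Dock3 and Dock4 were lower in library 2 (8.06 and 12.3 FPKM) than in library 1 (9.81 and 17.1) and library 3 (9.18 and 15.9), while the order of Dock4, Dock3, Dock11 and Dock1 was the same in all 3 libraries.

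**Figure D1:**
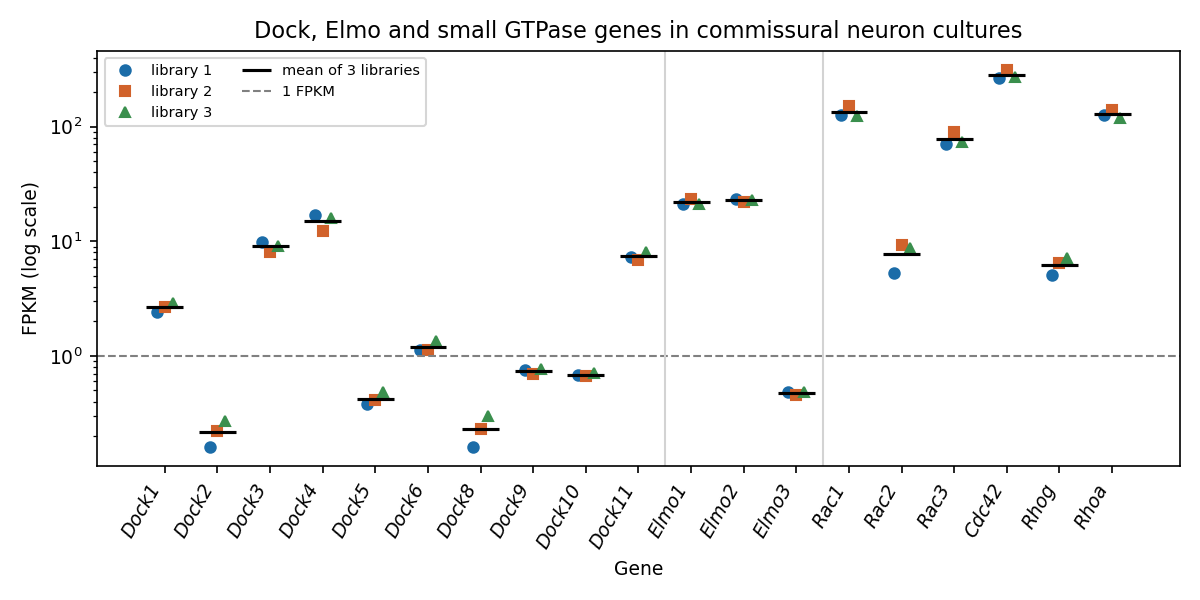
FPKM (vertical axis, log scale) of each reported gene of the Dock and Elmo families and of the small GTPases in the 3 libraries (symbols), with the mean of the 3 libraries (bars) and the level of 1 FPKM (dashed line). Dock4 had the highest mean of the Dock genes plotted, 15.1 FPKM, and Dock2 the lowest, 0.217 FPKM.

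Genes for the proteins that work with Dock factors were expressed as well. Elmo proteins bind several Dock proteins and form exchange factors with them. Elmo2 had 22.8 ± 0.755 FPKM and Elmo1 22.0 ± 1.36, and the pair did not differ past the threshold (log2 ratio of Elmo1 to Elmo2 -0.05, 95% interval -0.29 to 0.19; limma, Benjamini-Hochberg adjusted p = 0.584). Elmo3 had 0.473 ± 0.0115 FPKM, so 2 of 3 Elmo genes lay above 1 FPKM, and 2 when adjusted over the list alone. All 6 GTPases on the list lay above 1 FPKM (6 when adjusted over the list alone): Cdc42 had 283 ± 27.5, Rac1 133 ± 14.5, Rhoa 129 ± 10.3, Rac3 78.1 ± 10.0, Rac2 7.83 ± 2.18 and Rhog 6.25 ± 1.05 FPKM. Rac1 exceeded Rac3 by 1.71-fold (1.49 to 1.96, limma, Benjamini-Hochberg adjusted p = 4.05e-04, 3 of 3 libraries). Rac2, known mainly from blood cells, had 5.33 FPKM in library 1, 9.33 in library 2 and 8.82 in library 3. The macrophage marker Aif1 was also lowest in library 1 (5.08, 7.38 and 7.82 FPKM). Cx3cr1, another such marker, was lowest in library 3 (0.22, 0.35 and 0.15 FPKM). All 5 Crk and Cas adaptors, scaffolds that link Src kinases to Dock1, lay above 1 FPKM (5 when adjusted over the list alone), from Crk at 41.4 ± 2.53, Crkl at 34.5 ± 1.60 and Bcar1 at 28.4 ± 1.46 to Efs at 7.96 ± 0.418 and Nedd9 at 4.67 ± 0.260 FPKM. Of the 18 other exchange factors known to act on Rac, 14 lay above 1 FPKM (14 when adjusted over the list alone), led by Arhgef7 at 46.7 ± 0.815, Vav2 at 31.5 ± 0.251, Trio at 25.6 ± 4.22 and Vav3 at 21.2 ± 0.857 FPKM. Tiam2 (0.407 ± 0.0862) and Prex2 (0.397 ± 0.0404) were the lowest of them.

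The next question is which receptors for Shh the cultures express. Boc, a co-receptor for Shh, had 15.3 ± 0.396 FPKM, Cdon 9.16 ± 1.31 and Gas1 4.84 ± 0.522, and the 3 co-receptors differed from each other: Boc exceeded Cdon by 1.67-fold (1.35 to 2.07, limma, Benjamini-Hochberg adjusted p = 0.00241, 3 of 3 libraries) and Gas1 by 3.12-fold (2.59 to 3.77), and Cdon exceeded Gas1 by 1.87-fold (1.48 to 2.36). Smo, which carries the Shh signal into the cell, had 10.4 ± 0.837 and Ptch1, the receptor that holds Smo inactive, 10.1 ± 0.467 FPKM. Gpc1, a glypican, had 42.3 ± 0.405 FPKM and Lrp2 2.32 ± 0.539. These 7 of the 8 reception genes reported here lay above 1 FPKM, and 7 when adjusted over the list alone; Hhip, an inhibitor that binds Shh, had 0.533 ± 0.0924 FPKM. The difference between Boc and Cdon did not pass when a difference of at least 1.5-fold was tested.

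Of the Gli arm, which carries the transcriptional response to Shh, 4 of 5 genes lay above 1 FPKM, and 4 when adjusted over the list alone. Sufu had 7.63 ± 0.943, Gli3 3.75 ± 0.567, Kif7 2.15 ± 0.117 and Gli2 1.59 ± 0.228 FPKM; Gli2 did not pass without library 2 (limma, Benjamini-Hochberg adjusted p = 0.0532). Gli1, itself a target of Shh signalling, was listed at 0.01 FPKM in each library. Of the Src family kinases, which act in Shh-guided turning of axons, Fyn had 121 ± 8.0, Src 39.7 ± 2.83 and Yes1 7.52 ± 0.327 FPKM, and Fyn exceeded Src by 3.03-fold (2.63 to 3.49, limma, Benjamini-Hochberg adjusted p = 2.79e-05, 3 of 3 libraries). With Lyn (1.43 ± 0.439), 4 of the 7 kinases reported here passed (4 when adjusted over the list alone), but Lyn was lost when any 1 library was left out, with adjusted p of 0.0601, 0.207 and 0.184 in limma's Benjamini-Hochberg adjusted test without libraries 1, 2 and 3. Fgr had 0.797 ± 0.317 FPKM, and Blk was listed at 0, 0.02 and 0 FPKM. Of the 14-3-3 adaptors, 6 of 7 lay above 1 FPKM (6 when adjusted over the list alone): Ywhae had 614 ± 46.2, Ywhaz 478 ± 38.6, Ywhaq 342 ± 31.9 and Ywhag 276 ± 21.2 FPKM, while Sfn had 0.193 ± 0.0231. The genes for local translation of beta-actin all passed (4 of 4, and 4 when adjusted over the list alone), with Igf2bp2 at 19.2 ± 1.48, Igf2bp3 at 10.0 ± 0.791 and Igf2bp1 at 9.50 ± 0.792 FPKM beside Actb at 1854 ± 109.

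Receptors for other midline cues were compared next. All 25 matched guidance receptors lay above 1 FPKM (25 when adjusted over the list alone), with a median of 32.1 FPKM. Robo3, which holds off the response to Slit before crossing, had 104 ± 25.4 FPKM, and the netrin receptor Dcc 62.6 ± 12.7. L1cam had 50.3 ± 5.91 and Nrcam 48.0 ± 4.98, while Ephb3 (5.26 ± 0.268) and Unc5a (2.12 ± 0.416) were the lowest; Unc5a did not pass without library 2 (limma, Benjamini-Hochberg adjusted p = 0.0637). Robo3 exceeded Robo1 by 3.17-fold (2.5 to 4.02, limma, Benjamini-Hochberg adjusted p = 1.80e-04, 3 of 3 libraries) and Robo2 by 3.02-fold (2.39 to 3.83), while Robo1 and Robo2 did not differ past the threshold (log2 ratio -0.07, interval -0.26 to 0.13). Dcc exceeded its relative Neo1 by 1.45-fold (1.19 to 1.77, limma, Benjamini-Hochberg adjusted p = 0.00613, 3 of 3 libraries), a call that was lost when a difference of at least 1.5-fold was tested. Of the 21 pairs of netrin receptors, 20 differed past the threshold; Unc5b and Unc5d did not, but did without library 2, and Dscam and Unc5d no longer did without library 1.

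Robo3, Dcc and Cntn2 were lower in library 2 (74.5, 48.1 and 33.4 FPKM) than in library 1 (118, 68.0 and 44.2) and library 3 (119, 71.6 and 46.4). In the same library, 24 of 24 genes with very long transcripts were lower, with a median log2 deviation from libraries 1 and 3 of -1.03 after the median of all genes was subtracted. The ribosomal protein genes were higher by a median of 0.19 (68 genes), against 0.07 to 0.12 in random lists matched on expression. Boc did not share this, with 15.7 FPKM in library 2 against 15.0 and 15.1.

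**Figure D2:**
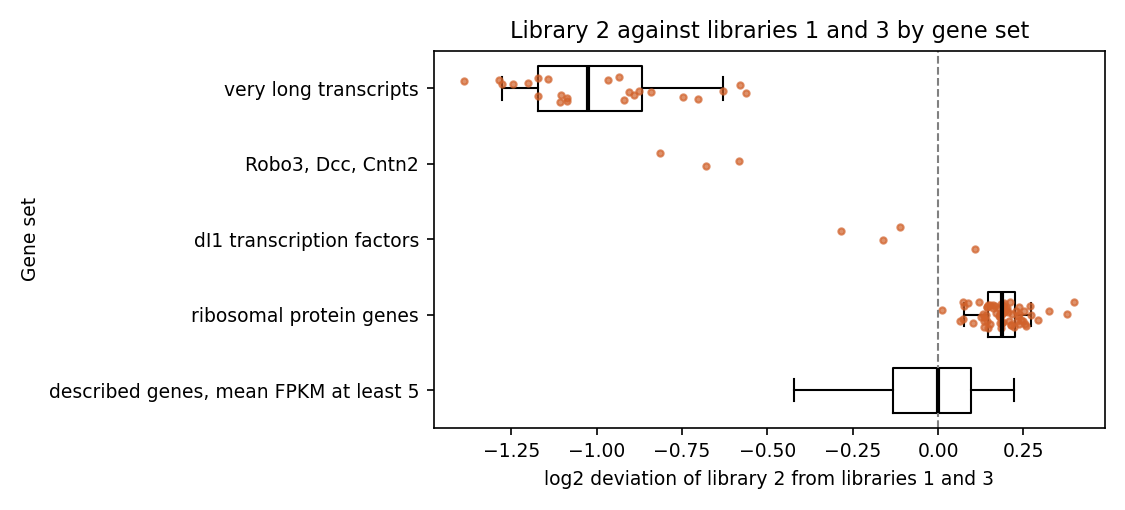
Log2 deviation of library 2 from the mean of libraries 1 and 3, with the median of all described genes subtracted (horizontal axis), for 5 sets of genes; points are genes, boxes the quartiles with the median, and whiskers the 5th and 95th percentiles. The 24 very long transcripts lay between -1.39 and -0.56, and the 68 ribosomal protein genes between 0.013 and 0.40.

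Of the guidance ligands, 12 of 16 lay above 1 FPKM, and 12 when adjusted over the list alone. Draxin, a secreted repellent, had 46.3 ± 3.4, Slit1 35.7 ± 3.42, Vegfa 25.1 ± 0.947 and Ntn1 18.5 ± 1.59 FPKM. Shh itself had 0.10 ± 0.0458 FPKM and Gdf7 was listed at 0.04, 0.04 and 0.

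Marker lists describe which cells the cultures held. All 12 pan-neuronal genes lay above 1 FPKM (12 when adjusted over the list alone), from Tubb3 at 960 ± 70.2, Stmn2 at 435 ± 41.0, Dcx at 423 ± 6.90 and Map2 at 193 ± 2.20 to Syt1 at 30.1 ± 0.766 and Rbfox3 at 27.0 ± 2.29 FPKM. All 4 commissural axon markers passed (4 when adjusted over the list alone): Robo3, Dcc, Boc and Cntn2, the last at 41.4 ± 6.94 FPKM. The 4 matched markers of dI1, a dorsal class that gives rise to commissural neurons, also passed (4 when adjusted over the list alone), with Pou4f1 at 61.9 ± 0.838, Barhl2 at 28.1 ± 3.25, Barhl1 at 19.0 ± 0.479 and Lhx9 at 4.96 ± 0.296 FPKM. Markers of the other dorsal classes dI2 to dI5 passed as well. The dI2 list passed in 4 of 4 genes, with Lhx1 at 69.6 ± 3.57, Lhx5 at 30.3 ± 5.03, Foxd3 at 13.6 ± 0.760 and Foxp2 at 6.37 ± 1.32 FPKM. The dI3 list passed in 4 of 4, with Tlx3 at 21.8 ± 2.89, Isl1 at 12.7 ± 0.269 and Drgx at 3.20 ± 1.04 beside Pou4f1. The dI4 list passed in 4 of 5, with Pax2 at 31.1 ± 0.395 and Lbx1 at 29.8 ± 3.90 FPKM beside Lhx1 and Lhx5, while Ptf1a was listed at 0.19, 0 and 0.08. The dI5 list passed in 4 of 5, with Lmx1b at 14.8 ± 2.91 beside Pou4f1, Lbx1 and Tlx3, while Phox2a had 0.23 ± 0.010 FPKM. Each of these counts was the same when adjusted over the list alone. Pou4f1, Lhx1, Lhx5, Tlx3, Lbx1 and Isl1 stand on more than 1 list, so the lists are not independent.

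The lists of dI6 and of the ventral classes were counted in the same way. The 2 V0 markers Evx2 (2.95 ± 0.742 FPKM) and Evx1 (1.70 ± 0.259) passed (2 when adjusted over the list alone), and Evx1 did not without library 2 (limma, Benjamini-Hochberg adjusted p = 0.0621). None of the 2 dI6, 1 V1, 3 V2 and 2 V3 markers reported here lay above 1 FPKM in limma's test, over all genes or when adjusted over the list alone, and 0 did at an unadjusted p under 0.05. Gata2, the highest of them, had 0.0267 ± 0.0153 FPKM, and En1, Dmrt3 and Sox14 were listed at 0 in each library. Of the motor neuron markers, 1 of 6 passed (1 when adjusted over the list alone), Isl1, which the dI3 list also holds, and Mnx1 and Isl2 were listed at 0 in each library. The mean log2(FPKM + 0.1) of the dI1 list exceeded that of 23 of 24 other cell class lists in each of the 3 libraries, by 0.24 ± 0.10 for the GABA and glycine list and 0.40 ± 0.13 for dI3. The exception was dI2, at -0.03 ± 0.03 (dI1 minus dI2). With the median over list members, the difference from dI2 turned to 0.19 and that from dI4 from 0.67 to -0.40. The means of dI4 and dI5 each include 1 gene far below their other members, Ptf1a (mean 0.09 FPKM) and Phox2a (0.23 FPKM). The order of the means therefore does not show that dI1 was the most abundant dorsal class. The commissural axon list exceeded 24 of 24, by 1.11 ± 0.23 for dI2 and 1.38 ± 0.21 for the GABA and glycine list. Its place in the order likewise does not show how abundant commissural neurons were.

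**Figure D3:**
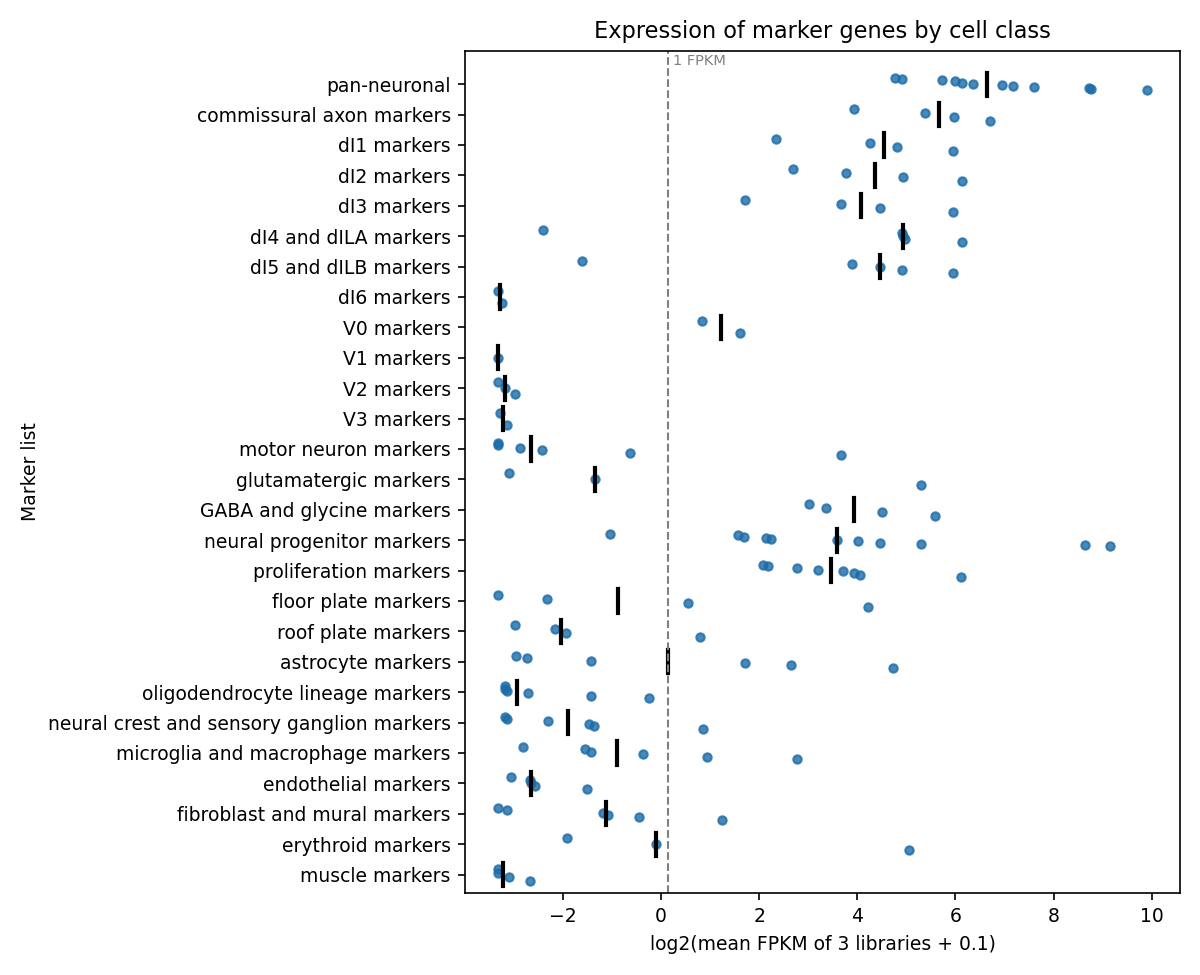
Log2 of mean FPKM plus 0.1 (horizontal axis) of each reported marker gene (points) by marker list (vertical axis), with each list's median (bars) and the level of 1 FPKM (dashed line); genes listed at 0 lie at the left edge. The 4 dI1 markers lay between Lhx9 at 4.96 and Pou4f1 at 61.9 FPKM.

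Both main transmitter types were represented. Slc17a6, the vesicular glutamate transporter of spinal neurons, had 39.5 ± 0.859 FPKM and was the 1 of 3 glutamatergic markers above 1 FPKM (1 when adjusted over the list alone). All 4 GABA and glycine markers passed (4 when adjusted over the list alone): Slc32a1 had 47.7 ± 3.49, Gad2 22.5 ± 2.29, Gad1 10.1 ± 1.82 and Slc6a5 7.95 ± 0.891 FPKM. Progenitor genes passed in 10 of 11 cases (10 when adjusted over the list alone), with Fabp7 at 564 ± 106, Vim at 398 ± 27.0, Sox2 at 39.3 ± 5.38 and Slc1a3 at 22.0 ± 0.660 FPKM, and Pax6 (2.86 ± 0.263) and Pax7 (0.387 ± 0.146) lowest. All 8 proliferation markers passed (8 when adjusted over the list alone), from Pcna at 69.4 ± 7.49, Cdk1 at 16.6 ± 2.01, Ccnb1 at 15.2 ± 1.11 and Top2a at 13.0 ± 0.882 to Mki67 at 4.46 ± 0.480 and Bub1 at 4.14 ± 0.344 FPKM.

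Markers of other cell types were mostly below 1 FPKM. Of the floor plate list, 2 of 4 passed, Ntn1 and Spon1 (1.37 ± 0.208 FPKM), and Foxa2 was listed at 0 in each library. Of the roof plate list, 1 of 4 passed, Wnt1 (1.65 ± 0.278). Of the astrocyte list, 3 of 6 passed, Slc1a2 (26.6 ± 1.64), Gja1 (6.22 ± 0.721) and Aldh1l1 (3.20 ± 0.467), and Aqp4 had 0.050 ± 0.010 FPKM. Of the 6 oligodendrocyte genes reported here, 0 passed in limma's test and 0 at an unadjusted p under 0.05, and Mbp, the highest of them, had 0.743 ± 0.232 FPKM. The neural crest and sensory ganglion list in 1 of 6, Calca (1.71 ± 0.282), and the fibroblast and mural list in 1 of 6, Col3a1 (2.27 ± 0.512). The microglia and macrophage list passed in 2 of 6, Aif1 (6.76 ± 1.47) and Csf1r (1.82 ± 0.569), and the erythroid list in 1 of 3, the alpha globin Hba1, at 56.9, 30.2 and 12.4 FPKM in libraries 1, 2 and 3. None of the 5 endothelial and 4 muscle markers passed in limma's test, and 0 did at an unadjusted p under 0.05; Pecam1, the highest, had 0.253 ± 0.0551 FPKM. The counts of these lists were the same when adjusted over the list alone. Wnt1 was lost without library 1, Calca without library 2, and Spon1 and Csf1r without library 2 or library 3, which left 0, 0, 1 and 1 genes of their lists. Of the stress and immediate early genes, 7 of 8 passed (7 when adjusted over the list alone), with Hspa5 at 99.0 ± 12, Jun at 50.1 ± 4.60, Ddit3 at 19.1 ± 2.75 and Gadd45a at 18.9 ± 1.77 FPKM, and Fos at 1.80 ± 0.312. Hspa1a was matched to an entry with the symbol Hspa1b, listed at 0, so that value is of the entry named Hspa1b. Egr1 (2.21 ± 1.03) was lost without library 1 or library 2, which left 6 genes.

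The highest entries of the table were features without a gene name. In library 1, 43 entries above 10000 FPKM made up 98.3% of the summed FPKM, against 35 entries with 97.6% in library 2 and 36 with 98.4% in library 3. The 10 highest, of which 9 carried no symbol and 1 was an entry named Nnat, reached means from 337945 to 7152910 FPKM. Among entries with a description, Tuba1a was highest at 5262 ± 467 FPKM, followed by the thymosin Tmsb10 at 3392 ± 406, ubiquitin B at 2676 ± 542 and Tmsb4x at 2314 ± 274. Stmn1, a regulator of microtubules, had 1889 ± 207 and Tubb5 1654 ± 102 FPKM.

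The libraries differed little in most genes. The SD of log2(FPKM + 0.1) was at least 0.5 in 152 of 8695 entries with a mean of at least 5 FPKM, and the 10 most variable carried no gene name and were at 0 in at least 1 library. Among entries with a description it was at least 0.5 in 46 of 8069, with a median of 0.12. Embryonic globin Hbe1 had 207, 127 and 28.1 FPKM in libraries 1, 2 and 3, Mt1a 23.8, 15.2 and 4.23, Apoe 3.20, 13.9 and 11.4, and Edil3 124, 36.6 and 34.0. Reln had 51.6, 22.4 and 53.1 and the protocadherin Fat3 11.99, 4.97 and 11.8 FPKM. Of the 46, 24 were lowest in library 2, 9 in library 1 and 13 in library 3.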

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

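Among the alternative settings, only the restriction to entries with a description was chosen after seeing the data. With each library rescaled to a common sum, 2363 genes instead of 11218 lay above 1 FPKM, 49 list genes instead of 164, and 67 variable genes instead of 152. Counts of genes reported fell there from 7 to 1 for Shh reception, from 25 to 10 for guidance receptors, from 12 to 2 for guidance ligands, from 14 to 1 for other Rac exchange factors, from 4 to 1 each for dI1 to dI5 and for GABA and glycine, from 10 to 3 for progenitors and from 8 to 1 for proliferation. In 12 lists, among them Dock (4 before), Elmo (2), the Gli arm (4), V0 (2) and astrocytes (3), 0 genes were left in limma's test and 0 at an unadjusted p under 0.05. All this follows from the construction, since a few unnamed features hold most of each sum. With described entries alone, 46 variable genes were left, because the unnamed ones were removed. With medians over list members, dI1 minus dI2 turned from -0.03 to 0.19 and dI1 minus dI4 from 0.67 to -0.40. The dI4 list holds 1 low gene, Ptf1a at 0.09 FPKM beside members from 29.8 to 69.6, which weighs on the mean and little on the median. The cause of the change for dI2 was not tested. Of the 48 differences between cell class lists, 36 others moved by more than their SD between libraries with medians, 33 with a pseudocount of 0.01 and 40 with a pseudocount of 1, none of these with a change of sign. Leaving out 1 library gave 10942 to 11068 genes above 1 FPKM. Of the 10 Dock genes reported, 4 passed with either pseudocount, a common upper quartile, each other filter and without any 1 library, 5 with a prior without trend, 7 at a level of 0.5 FPKM and 3 at 5 FPKM. In 1 further comparison of a planned pair, 0 pairs instead of 1 passed with a pseudocount of 0.01, and 0 to 1 when 1 library was left out; the cause was not tested. Of the 84 pairs of genes reported, 66 passed instead of 79 with a margin of 1.5-fold. No pair reversed its direction in any setting. No paired analysis was possible because the series has 1 group. The absolute depth is not given by FPKM, so whether low genes such as Dock2 or Gli1 were limited by depth could not be judged.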

Other observations

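Families outside the fixed lists were looked at after the data were seen. Of 36 Hox genes, which mark position along the body axis, 22 lay above 1 FPKM in limma's test. The summed FPKM was highest in paralog groups 8 (458 ± 52.2) and 9 (340 ± 50.7), led by Hoxb8 at 370 ± 46.0 and Hoxb9 at 280 ± 44.1, and groups 2 to 7 ranged from 85.9 (group 4) to 194 (group 6). Group 1 summed to 1.66 ± 0.05 with 0 of 3 genes above 1 FPKM in limma's test, and groups 11 and 12 were listed at 0 in each library. Of 8 ephrins, 7 lay above 1 FPKM, led by Efnb3 at 43.2 ± 3.62 and Efnb2 at 36.1 ± 1.76, and of 14 Eph receptors 10, led by Ephb2 at 37.8 ± 0.905. Of 20 semaphorins 17 did, led by Sema6c at 54.2 ± 3.38, and of 23 cadherins 11, led by Cdh2 at 119 ± 1.89.

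Of the tests below, those of the dI1 factors, of the globins and both on the Hox genes were chosen after their values were seen. They therefore decide neither for nor against an explanation. The design gives no groups, so no biological explanation was tested against a group.

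Robo3, Dcc and Cntn2 were lower in library 2, with a mean log2 deviation of -0.69. Whether fewer dI1 neurons were the whole cause was not decided. The 4 dI1 factors deviated by -0.11 (SE over genes 0.082), from -0.29 for Lhx9 to 0.11 for Barhl2, where -0.35 or lower was needed. That bound was set after the values were seen, and Pou4f1 also stands on other lists. A shift with transcript length in library 2 could have raised these factors, which was not tested. A candidate explanation is a loss of long transcripts in library 2. The 24 of 42 listed very long transcripts with a mean of at least 5 FPKM had a median deviation of -1.03, against -0.09 to 0.06 in random lists matched on expression, while library 3 differed from library 1 by -0.07, much less but also below its own matched range (-0.04 to 0.05) and with 21 of 24 genes below 0. That list was written before its values were seen, but Fat3 stood among the most variable genes and lower values of Trio and Kalrn in library 2 were already known. Degraded RNA and a difference in library preparation would both do this and remain open, as does a change in the axonal genes themselves.

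Genes known from blood cells differed between libraries. Rac2, Vav1, Fgr, Lyn, Dock2 and Dock8 were lower in library 1 in 6 of 6 cases (median log2 deviation -0.58). A candidate source is a small amount of macrophage or microglia RNA. Against the mean log2 value of libraries 2 and 3, 16 of 16 other macrophage genes were lower in library 1. Their median deviation was -0.66 after the median of all genes was subtracted. The most abundant were Coro1a at 14.2, Lyz2 at 10.8 and Fcer1g at 9.71 FPKM. Library 1 was not below library 3 in every gene. C1qc had 0.10 FPKM in both, and Cx3cr1 of the fixed list had 0.22 FPKM in library 1 and 0.15 in library 3. The macrophage test was written before its values were seen, but Fcer1g stood among the most variable genes. Neurons may also express some of the blood-cell and macrophage genes, so the share of each that comes from other cells stays open. Carry-over of red cell RNA predicts 1 order of libraries for all globin and erythroid genes, and 80% (8 of 10, not Hbb or Gypc) were highest in library 1 and lowest in library 3. That value equals the bound set for it and most of its genes had been seen to vary, so the globins decide nothing here.

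Hox genes of groups 8 to 10 were higher in library 2 relative to groups 2 to 5, by a mean log2 difference of 0.72 (7 against 11 genes with a mean of at least 1 FPKM), with 10 of 11 genes of groups 2 to 5 below 0 (mean -0.31). Hoxc10 (0.39, 2.40 and 0.48 FPKM) entered only through its value in library 2, and without it the mean of groups 8 to 10 was 0.13 and the difference 0.44, against 0.08 between libraries 3 and 1. A slightly more caudal piece of spinal cord in library 2 may account for this, but the split of the genes was chosen from these values, so it cannot be told apart from other causes. A loss of long transcripts stays open too: the median deviation of groups 8 to 10, 0.16, decides nothing, since it was set against the range of single ribosomal protein genes and left out groups 2 to 5. Hoxd9, at 0.15, 1.94 and 0.31 FPKM, was below the level needed to enter.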
